A study of Homo sapiens with 3 samples.

How the data were processed

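RNA sequencing was analysed for PLC cells, a human liver cancer cell line per the labels, in 3 libraries: NTC, shHKDC1 and shRBBP5, with 1 library per group. Per the labels, total RNA was extracted with TRIzol and reverse transcribed with HiScript III RT SuperMix (Vazyme). HISAT2 2.2.1, StringTie 1.3.4, DESeq2 1.28.1 and the genome build hg19 are named in the submitters' processing notes, without a role or order for each. The deposited table holds estimated counts (expected counts) per row, not scaled for library size or transcript length. Its 3 columns carry the abbreviations NTC, shHD and shRB, which were mapped to NTC, shHKDC1 and shRBBP5 by those abbreviations. The annotation, strand setting and the tool that wrote the counts are not given in the sources used here.

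The table has 43704 rows, of which 16301 are anonymous loci numbered by the assembly and 27403 are RefSeq transcripts. Anonymous loci held 99.43% of the units in NTC, 99.60% in shHKDC1 and 99.53% in shRBBP5. RefSeq accessions were matched to gene symbols without their version number in a GRCh38 RefSeq annotation, which named 27357 transcript rows and left 46 unmatched. Because the table was made on hg19, no coordinates were used, and the anonymous loci were not given names. RefSeq rows were summed per gene, and a gene was used only when every one of its RefSeq transcripts had a row of its own, which held for 11642 of 12034 symbols. The other 392 were kept apart as partly named genes. Summing was chosen after the table was seen, because 115 of the 596 transcript rows that reached 500 units in some library had 0 in another. After summing, 0 of 553 genes that reached 500 units did so, against 19 of 11485 anonymous loci.

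Totals were 161750310 units in NTC, 115556160 in shHKDC1 and 154533913 in shRBBP5. Low values piled up at 4, so that 525 rows of NTC held 4 units, 332 held 3 and 235 held 5. There was no such peak at 8, with 254 rows of NTC at 7 units, 227 at 8 and 162 at 9. That 1 sequenced fragment is worth 4 units is therefore an assumption, made after the values were seen, and every interval and fragment number rests on it. It gives 40437578, 28889040 and 38633478 fragments. The design had assumed plain counts, and treating each unit as a read, which narrows the intervals, was run as an alternative. The 20 most abundant rows took 10.02%, 10.69% and 9.31% of the units in NTC, shHKDC1 and shRBBP5. Across anonymous loci averaging at least 100 units, log2 values correlated at r = 0.919 between NTC and shHKDC1, 0.966 between NTC and shRBBP5, and 0.924 between the knockdowns. These correlations run across loci within 1 library pair, and loci are not independent replicates.

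Libraries were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.083 for NTC, 0.894 for shHKDC1 and 1.032 for shRBBP5. CPM values (counts scaled to library size) and log2 ratios used these scaled sizes, with a pseudocount of 0.5 units in the ratios. A feature was measured when its mean CPM over the 3 libraries was at least 1. It was called higher or lower when its log2 ratio was at least 1 in size and its exact 95% Clopper-Pearson interval, from a conditional binomial on fragments, excluded 0. With 1 library per group no test of differences between groups was made and no p-value or standard error is given. The intervals cover counting error only. They may be too narrow even for that, since reads without molecular identifiers are not independent molecules. At this depth, 3 fragments (12 units) corresponded to 0.0742 CPM in NTC, 0.104 in shHKDC1 and 0.0777 in shRBBP5 before scaling. Other steps used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.

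The 3 comparisons, the 2-fold rule, 46 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named the 12 highest and 12 lowest protein-coding genes per knockdown among those called with a mean CPM of at least 5, or all where fewer were called. It took 6 each way for the direct comparison, 10 each way for both knockdowns together, hexokinases, subunits of H3K4 methyltransferase complexes, and up to 4 members of a described list at that CPM. Genes below a mean CPM of 5 that are named in the text were chosen after their values were seen, except hexokinases and H3K4 methyltransferase subunits. List medians were placed among 10000 random lists of the same size drawn from 20 bins of mean CPM, for lists with at least 3 measured members. Another 8 gene lists were written after values had been seen, and their results stand in the closing section only.

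The rule was tested on simulated data with counting noise alone, in which it recovered 100% of planted 3-fold, 4-fold and 8-fold differences and 0% to 4% of 1.5-fold ones. It made 0 to 3 false calls among 12155 unchanged loci or 815 unchanged genes per comparison, and the intervals covered the true ratio in 95.2% to 95.9% of features. Real differences between libraries of the same kind add to counting noise, and these simulations leave that out.

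The alternatives were total-count, DESeq2 1.42.0 size-factor and upper-quartile scaling, leaving out the 20 most abundant rows, a mean CPM of at least 5 or no filter, a pseudocount of 5 units, a 1.5-fold rule, and splitting the NTC fragments between the knockdowns. Mitochondrial genes were to be left out with the top rows, but 0 rows carried a mitochondrial name. Added after the data were seen were units taken as reads, RefSeq rows not summed, partly named genes added, and removal of a loess trend on GC content or transcript length from list values. HKDC1, RBBP5, MYC, ALB and AFP had no rows of their own among the RefSeq transcripts, so the planned check of the targeted transcripts was left out.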

Results

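RNA from PLC cells was sequenced in 1 library each for NTC, shHKDC1 and shRBBP5, to ask whether HKDC1 and RBBP5 regulate gene expression. The 13370 measured features comprised 12355 anonymous loci and 1015 named genes, 913 of them protein coding. Named genes were a selected, low-abundance minority, with a median of 2.60 CPM against 28.1 CPM for the loci. Each value of a named gene covers its RefSeq rows alone. Whether further reads of that gene lay in an anonymous locus was not tested. HKDC1, RBBP5, MYC, ALB and AFP had no rows of their own, so the loss of the targeted transcripts was not analysed here. There were no replicates, so no difference has a replicate check, and the 95% intervals in brackets cover counting error only.

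In the shHKDC1 library, VLDLR, the receptor that takes up triglyceride-rich lipoproteins, was 5.88-fold higher than in NTC, at 18.3 against 3.11 CPM (log2 2.55 [2.28 to 2.84]). The Wnt inhibitor NKD1 was higher as well (log2 1.14 [0.89 to 1.40]). PLXNC1, a semaphorin receptor, was 12.3-fold lower, at 0.832 against 10.3 CPM (log2 −3.62 [−4.28 to −2.98]). VLDLR and NKD1 were the 2 genes called higher among the 211 protein-coding genes with a mean CPM of at least 5, while 46 were called lower. A gene low in 1 library alone passes this filter on its level in the other libraries. The filter itself can therefore favour genes low in a knockdown over genes high in it. How far it did so was not tested, here or in the later comparisons, and with no CPM filter the balance of named genes turned.

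The sulfate transporter SLC26A2 had a log2 ratio of −2.62 [−3.12 to −2.17], the early endosome tether EEA1 −2.45 [−2.90 to −2.03], and the lipid transfer protein VPS13A −2.01 [−2.39 to −1.63]. SLC16A10, a transporter of aromatic amino acids, stood at −1.60 [−1.94 to −1.27]. EVC, a ciliary protein of Hedgehog signalling, was at 6.35 CPM in shHKDC1 against 26.8 CPM in NTC (log2 −2.08 [−2.32 to −1.84]). CENPE, a kinetochore motor, was 4.01-fold lower, and MYBL1, a transcription factor of the MYB family, had a ratio of −1.94. REV3L, the catalytic subunit of DNA polymerase zeta, was at −1.77, and SYNE2, a nuclear envelope protein, at −1.61. COBLL1 at −2.06 and FCGBP, a secreted mucin-like protein, at −1.53 complete the 12. Across 984 named genes, these ratios fell weakly with transcript length (Spearman rho −0.19) and rose weakly with GC content (0.13). For shRBBP5 over NTC the values were −0.12 and 0.20. The ratios of single genes were not corrected for either trend.

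Of 1006 genes on the 46 lists, 36 were measured, and 10 of these were higher, 9 lower and 17 neither in shHKDC1 than in NTC. List members with a mean CPM below 5, other than HK2, were chosen for naming after their values were seen. Among the hexokinases only HK2 was measured, at 5.59 CPM in shHKDC1 against 1.69 in NTC (log2 1.73 [1.31 to 2.15]). PKLR, the liver pyruvate kinase and the other measured glycolysis gene, was lower (−3.53 [−5.99 to −2.06]), on about 3 fragments in shHKDC1. BDH1, an enzyme of ketone-body metabolism, was lower (−3.42 [−4.78 to −2.36]). Both measured hepatocyte secreted genes, fibrinogen FGB and coagulation factor F5, were lower. FGB stood at 0.60 against 2.41 CPM (log2 interval −2.82 to −1.20), and F5 had a ratio of −1.82 [−2.45 to −1.19].

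The mesenchymal list was the only fixed list with at least 3 measured genes, and 2 of its 5 were higher, among them the matrix protein THBS1 (1.97 [1.53 to 2.45]). The other 3 were neither, and the list median of 0.51 lay at percentile 95.1 of matched random lists, inside the central 95%. The epithelial cadherin CDH1 was lower (−1.77 [−2.33 to −1.29]), and the other measured junction gene, claudin CLDN4, was neither (−0.10 [−0.70 to 0.54]). Both measured YAP targets were higher: NT5E, which makes adenosine (2.48 [2.02 to 2.98]), and AMOTL1, a junction protein (1.49 [0.86 to 2.14]). The cytokine LIF (2.76), the interferon-induced OASL (1.42) and the growth factor receptor PDGFRB (1.29) were higher, and osteopontin SPP1 (−3.03) was lower. RIGI, the other measured interferon-response gene, was neither (0.14, and −0.14 with total-count scaling). SESN1, a p53-induced stress gene, was lower (−1.45 [−1.88 to −1.05]), while the p53 target ZMAT3 (−0.98, and −1.26 with total-count scaling) and the Wnt target AXIN2 (−0.51) were neither. BOD1L1, the single measured subunit linked to the H3K4 methyltransferases, was not called (−0.69 [−0.96 to −0.43]).

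**Figure D1:**
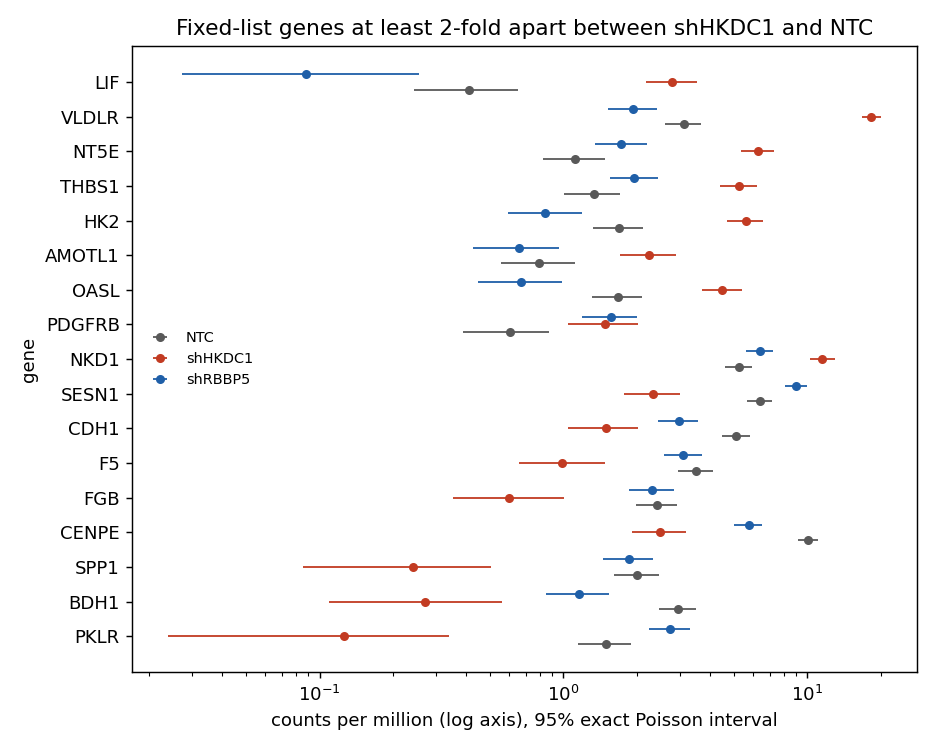
Level in CPM on a log axis for 17 of the 19 fixed-list genes at least 2-fold apart between shHKDC1 and NTC, with 1 point per library and 95% exact Poisson intervals. VLDLR, at 18.3 CPM in shHKDC1, has the highest level, and LIF, at 0.0878 CPM in shRBBP5, the lowest drawn.

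Over all features, 1065 were higher and 1606 lower in shHKDC1 than in NTC. Anonymous loci divided into 980 higher and 1371 lower with a median log2 ratio of −0.01, and named genes into 85 higher and 235 lower with a median of −0.39. MSTRG.13601 stood at 13.6 CPM in shHKDC1 on about 3 fragments in NTC (log2 7.46 [6.08 to 9.92]), and MSTRG.8533 at 0.581 against 19.8 CPM (−5.08 [−5.93 to −4.36]). Total-count scaling moved the median of all features from −0.03 to −0.31 and ended the call of NKD1 (0.86). With it, the higher share of calls went from 41.7% to 19.2% for loci and from 26.6% to 14.5% for named genes, while with no CPM filter the balance of named genes turned, to 557 higher and 473 lower with a median of 0.00.

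**Figure D2:**
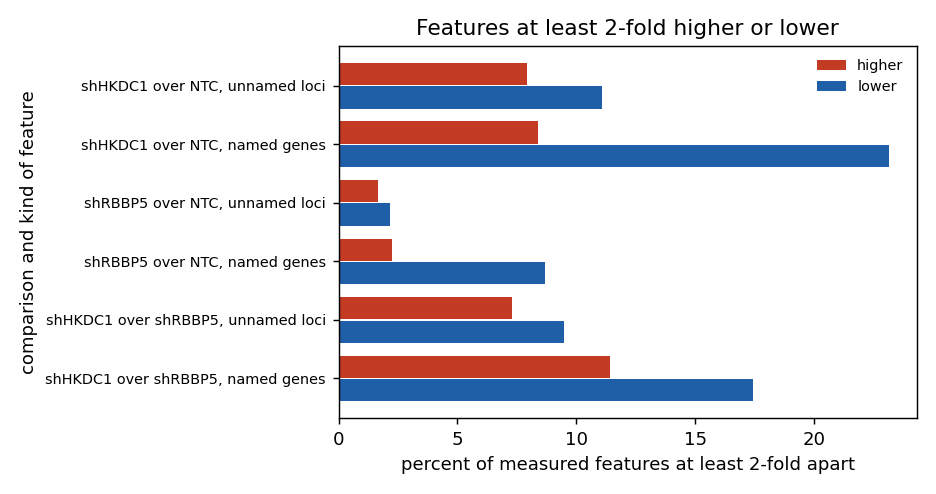
Percent of measured anonymous loci (labelled unnamed) and named genes at least 2-fold higher or lower in each comparison of 2 libraries. Named genes were lower more often than loci against NTC, at 23.15% against 11.1% in shHKDC1 and 8.67% against 2.18% in shRBBP5.

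In the shRBBP5 library, RAPGEF6, an exchange factor for Rap GTPases, was 3.71-fold lower than in NTC, at 2.53 against 9.39 CPM (log2 −1.89 [−2.22 to −1.58]). FCGBP had a ratio of −1.23, the chromatin remodeller CHD9 −1.16 [−1.44 to −0.90], VPS13A −1.08 [−1.33 to −0.84] and SLC26A2 −1.05 [−1.31 to −0.81]. PYGO1, a Wnt co-activator that binds methylated H3K4, was at −1.01 [−1.26 to −0.76], and N4BP2 was at 3.95 against 7.91 CPM (log2 interval −1.28 to −0.72). These 7 were the genes called lower among the 211 with a mean CPM of at least 5, and 0 were called higher.

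Of the 36 measured list genes, 1 was higher, 8 were lower and 27 were neither in shRBBP5. All 9 had a mean CPM below 5, and all but HK2 were chosen after their values were seen. PDGFRB was higher (1.36 [0.71 to 2.11]). LIF was lower (−2.18 [−4.06 to −0.43]), on 3 to 4 fragments in shRBBP5. The intestinal transcription factor CDX2 was at −1.48, BDH1 at −1.35, OASL at −1.31, the melanocyte transcription factor MITF at −1.28 and the DNA demethylase TET2 at −1.11. HK2 was at 0.840 against 1.69 CPM (−1.01 [−1.62 to −0.38]), and its call, like that of N4BP2, was lost with DESeq2 size factors. BOD1L1 was not called (−0.53 [−0.75 to −0.31]). The mesenchymal list had 0 higher and 1 lower gene and a median of −0.38, at percentile 33.4.

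Over all features, 231 were higher and 357 lower in shRBBP5. Loci divided into 208 higher and 269 lower (median 0.02), and named genes into 23 higher and 88 lower (median −0.20). MSTRG.13601 was higher on about 3 fragments in NTC (log2 6.73 [5.35 to 9.19]), and MSTRG.13823 stood at 0.163 against 8.24 CPM (−5.63 [−7.23 to −4.64]). Total-count scaling took the higher share of calls among loci from 43.6% to 32.6%.

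Compared directly, shHKDC1 exceeded shRBBP5 for VLDLR (log2 3.25 [2.89 to 3.61]), RAPGEF6 (1.43 [1.08 to 1.80]) and TRIM56, a ubiquitin ligase of innate immunity (1.07 [0.81 to 1.32]). These were the 3 genes called higher among the 211, and 30 were called lower. PLXNC1 had a ratio of −3.63 [−4.29 to −2.99], SESN1 −1.95 [−2.37 to −1.56] and SLC16A10 −1.68 [−2.02 to −1.35]. QRICH2, a sperm flagellum gene, was at −1.56, like SLC26A2, and EEA1 at −1.45. HK2 was 6.64-fold higher in shHKDC1 than in shRBBP5 (2.73 [2.16 to 3.29]), and 10 list genes were higher, 10 lower and 16 neither. The mesenchymal list had 2 higher and 1 lower gene and a median of 0.89, at percentile 96.7.

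Over all features the direct comparison gave 1017 higher and 1349 lower, and 11.43% of named genes were higher and 17.44% lower. The median log2 ratio was −0.04 for all features and −0.14 for named genes. Total-count scaling moved the median of all features to −0.25, ended the call of TRIM56 (0.86), and took the higher share of calls from 43.5% to 25.9% for loci and from 39.6% to 25.7% for named genes. Upper-quartile scaling took the share for loci to 54.3%, and with no CPM filter 660 named genes were higher and 390 lower.

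FCGBP, VPS13A, CHD9, SLC26A2 and N4BP2 were the 5 genes of the 211 called lower in both knockdowns, and 0 were called higher in both. CHD9 had nearly equal ratios, −1.08 [−1.40 to −0.77] in shHKDC1 and −1.16 in shRBBP5, although upper-quartile scaling put the first at −0.9985, just short of the call. EEA1, lower in shHKDC1, missed the call in shRBBP5 narrowly (−0.9993 [−1.24 to −0.77]). The shRBBP5 calls of N4BP2 and HK2 ended with DESeq2 size factors or a pseudocount of 5. SLC26A2 and VPS13A were lower by more in shHKDC1. HK2, LIF and OASL were among the genes called in opposite directions, higher in shHKDC1 and lower in shRBBP5.

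Among all features 90 were higher in both knockdowns, where independent calls would give 18.4, and 129 were lower in both, against 42.9. Another 52 were higher in shHKDC1 and lower in shRBBP5, against 28.4 for independent calls, and 20 the reverse, against 27.7. Total-count scaling moved the loci shared from 82 to 53 higher and from 98 to 157 lower, and the named genes from 8 to 5 and from 31 to 49. Across features, which are not independent replicates, the log2 ratios correlated at r = 0.34 (Spearman rho 0.37, covariance 0.207). Named genes alone gave r = 0.11 (covariance 0.0730), with 8 higher and 31 lower in both where independent calls would give 1.93 and 20.4. Of the named genes, 13 were higher in shHKDC1 and lower in shRBBP5, against 7.37 for independent calls, and 5 the reverse, against 5.33. Both ratios share the NTC library, and simulated unchanged libraries gave r = 0.42 with covariance 0.0062 from counting error alone, and r = 0.49 with covariance 0.0917 at an assumed coefficient of variation of 0.2. At that assumed variation the unchanged libraries gave 29.8 features higher and 12.2 lower in both, and 4.24 and 1.82 among named genes. The control is 1 library and cannot be split into 2 groups of libraries, so part of the excess may come from the shared control.

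**Figure D3:**
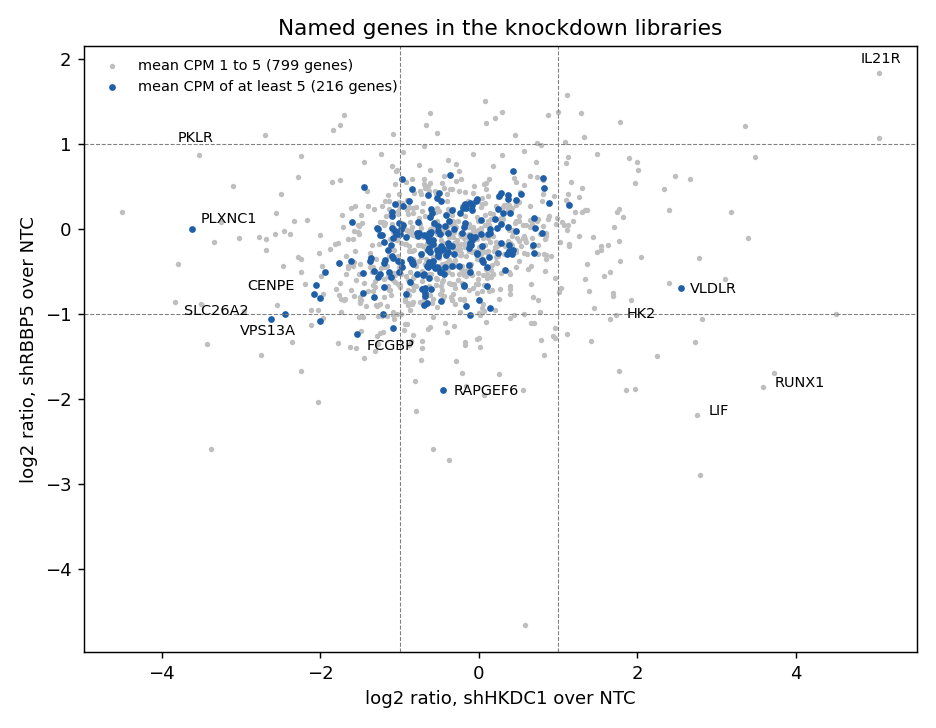
Log2 ratio of shRBBP5 over NTC against that of shHKDC1 over NTC for the 1015 named genes, 1 point per gene, with dashed lines at 2-fold. VLDLR lies to the right and PLXNC1 to the left near 0 on the vertical axis, and the lower right holds LIF; some labelled genes were chosen after their values were seen.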

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

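The test of variation between NTC libraries was chosen after the overlap of the knockdowns had been seen, and the other tests of the 2 patterns in this part were set before.

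Genes outside the comparisons, those with some transcripts on rows of their own and the rest not, were examined as well, and 74 were measured. In shHKDC1, 4 of the 74 were at least 2-fold higher than in NTC and 21 lower. Among the named genes, 8.37% were higher and 23.15% lower, and a difference from these shares was not tested. The 4 were EFNA5, an ephrin ligand (log2 1.02 [0.40 to 1.62]), FHL1, a LIM-domain protein (1.39 [0.68 to 2.09]), MYLIP, a ubiquitin ligase for lipoprotein receptors (1.11 [0.59 to 1.60]), and RNF125, a ubiquitin ligase (1.51 [0.99 to 2.05]). Total-count scaling ended the calls of EFNA5 and MYLIP. Among the 21 were coagulation factor F11 (−2.56), the microtubule-associated MAP1A (−2.94), STAT5A (−2.09) and the Wnt regulator APC (−1.34). In shRBBP5, 6 of the 74 were lower, among them F11 (−2.16) and APC (−1.15), where 8.67% of named genes were lower. Each value covers the named part of the gene alone, and these genes were named after their values were seen.

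Named genes lay below the anonymous loci in shHKDC1 against NTC, with medians of −0.39 and −0.01. Loci matched to the named genes on mean CPM had a median of −0.14, range −0.25 to 0.00 over the draws, which was 0.25 above the named genes. Among features past the filter, mean CPM alone therefore does not account for all of the gap. The matching was made after the filter, so it cannot tell whether the filter itself acted differently on named genes and loci. With no CPM filter the median of named genes was 0.00 and higher calls outnumbered lower ones, 557 to 473. That setting adds genes with very few units, and a gene with 0 units in both libraries has a ratio of exactly 0. The median of the loci was not taken without the filter, so whether the gap holds there stays open. Thinning NTC to the depth of shHKDC1 left 101.3% of the gap, but thinning leaves expected ratios as they are, so library depth stays open. How the reads of a gene were divided between its locus and its transcripts was not tested, and neither was a biological explanation.

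More features were called in the same direction in both knockdowns than independent calls would give, 90 higher and 129 lower. Splitting the NTC fragments between the knockdowns left 96.8% of the covariance over all features and 79.7% among named genes. In unchanged libraries, counting error alone gave 3.0% and 28.6% of the observed covariance. Counting error in the shared NTC library therefore does not account for most of it. Variation of that 1 library about the level of its group could give all of the covariance over all features at a coefficient of variation of 0.310. With 1 NTC library this cannot be told apart from a response common to the knockdowns. Among named genes the observed covariance of 0.0730 lay below the 0.108 simulated with unchanged libraries at an assumed coefficient of variation of 0.2.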

How the results depend on the processing

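Added after the data were seen were the settings with units taken as reads, RefSeq rows not summed, partly named genes added, and GC or length trends removed. Leaving out the 20 most abundant rows, a pseudocount of 5, DESeq2 size factors, units taken as reads, upper-quartile scaling and partly named genes kept every count of calls within 1.5 times its value, although medians near 0 and shares of calls moved under some scalings. Of 59 calls in shHKDC1 for features named in the text, total counts ended those of NKD1 (0.86), EFNA5 and MYLIP, and upper-quartile scaling that of CHD9 (−0.9985). Of 28 calls in shRBBP5, DESeq2 size factors and a pseudocount of 5 each ended those of N4BP2 (−0.994 and −0.996) and HK2 (−0.998 and −0.979), and of 50 direct calls total counts ended those of TRIM56 (0.86) and IRS2 (0.93). Medians of all features changed sign near 0, from −0.03 to 0.00 with DESeq2 size factors and 0.05 with upper quartiles in shHKDC1, from 0.01 to −0.06 with total counts and −0.03 with upper quartiles in shRBBP5, and from −0.04 to 0.07 with upper quartiles in the direct comparison. A rule that set such medians near 0 apart from reversals was adopted after these changes of sign were seen. The check of the targeted transcripts was not run, because HKDC1 and RBBP5 had no rows of their own.

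With total counts, loci in shHKDC1 divided into 543 higher and 2290 lower, where TMM gave 980 and 1371. Loci shared by the knockdowns went to 53 higher and 157 lower, and shared named genes to 5 and 49. Dropping the TMM factors, 0.894 for shHKDC1 and 1.083 for NTC, lowers every ratio of these libraries.

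With a mean CPM of at least 5, fewer features were tested, 216 named genes of 1015. Named genes then gave 2 higher and 48 lower in shHKDC1, 0 and 7 in shRBBP5, and 3 and 32 in the direct comparison, and loci in shRBBP5 gave 113 and 157. Shared calls were 43 and 52 for loci and 0 and 5 for named genes. The correlation became 0.374 for loci and 0.311 for named genes (0.356 and 0.114 before), and the cause was not tested. Of the lists written after values were seen, the median less that of the other genes reversed in shRBBP5 for matrix and adhesion genes (0.40 to −0.10) and zinc finger genes (−0.10 to 0.13), and the cause was not tested.

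With no filter, features below a mean CPM of 1 were added. Named genes gave 557 higher and 473 lower in shHKDC1, 134 and 291 in shRBBP5, and 660 and 390 in the direct comparison, so that higher calls became the more frequent in 2 comparisons. Loci lower in shRBBP5 came to 412 and loci lower in both to 166, and shared named genes to 37 higher and 85 lower. The correlations were 0.374 for loci and 0.320 for named genes, and the cause was not tested. In shHKDC1 the list difference reversed for innate immune genes (0.30 to −0.10) and zinc finger genes (0.18 to −0.24), as the median of all named genes went from −0.39 to 0.00.

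The 1.5-fold rule lowers the threshold by construction. Higher and lower loci were 2489 and 2831 in shHKDC1, 978 and 1063 in shRBBP5, and 1981 and 2511 directly. Higher and lower named genes were 142 and 399, 62 and 231, and 207 and 290. Shared calls were 417 and 521 for loci and 21 and 124 for named genes.

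With RefSeq rows not summed, higher and lower transcript rows numbered 214 and 405 in shHKDC1, 133 and 210 in shRBBP5, and 223 and 343 directly, with 76 and 98 shared and r = 0.409. The cause was not tested. List values moved by more than counting error 25 times under CPM filters or trend removal, besides the 4 reversals given. Depth limits the named genes most, with a median of 2.60 CPM against 28.1 for loci, and a call on about 3 fragments, such as that of PKLR in shHKDC1, has an interval several log2 units wide.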

Other observations

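The gene lists in this part were written after values had been seen, and the comparison of members seen and not seen beforehand was also chosen afterwards, whereas the GC and length tests were set before their results.

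The genes in this paragraph were chosen for their values and had a mean CPM below 5. The cytokine receptor IL21R stood at 3.69 CPM in shHKDC1 against 0.108 in NTC (log2 5.04 [3.74 to 6.67]) and was higher in shRBBP5 as well (1.83 [0.30 to 3.62]), while LIFR, the receptor of LIF, stood at 0.184 against 2.67 (−3.84 [−5.44 to −2.52]). IL22RA1, an interleukin 22 receptor chain, was lower as well (−3.34 [−4.95 to −2.01]). RUNX1 and ETS1, transcription factors of blood and vessel development, were higher in shHKDC1 (3.59 [3.02 to 4.25] and 2.82 [2.38 to 3.29]) and lower in shRBBP5 (−1.86 and −1.05). The homeobox gene HMX3 was higher in shHKDC1 (3.73 [2.87 to 4.66]), and SIX4 was lower (−1.65 [−2.17 to −1.16]). LAMB3, a laminin chain, was higher in both knockdowns (3.36 and 1.22), and the basement membrane collagen COL4A2 was higher in shHKDC1 (3.48 [2.47 to 4.57]).

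Genes of glucose sensing and insulin signalling divided between directions, with 2 of 15 higher and 4 lower in shHKDC1. IRS2, an insulin receptor substrate, was higher (1.37 [0.98 to 1.76]), and PIK3R1, a regulatory subunit of PI3-kinase, was lower (−1.49 [−1.94 to −1.06]). TXNIP, a glucose-induced inhibitor of glucose uptake, was lower in shHKDC1 (−2.69 [−4.32 to −1.63]) and higher in shRBBP5 (1.11 [0.70 to 1.54]). PDK4, which inhibits pyruvate dehydrogenase, was called in shRBBP5 alone (−2.14). The list median of −0.66 lay at percentile 16.4 of matched random lists.

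Cilium and centrosome genes had a median of −0.68 in shHKDC1 with 15 of 48 lower and 0 higher, at percentile 2.18. FAM161A (−2.33), ANKRD26 (−2.11) and the centriole duplication protein CEP152 (−1.42) were among them, and MAP9 was lower in shRBBP5 (−1.78). Of all named genes, 23.15% were lower and 8.37% higher in shHKDC1, and a difference from these shares was not tested. Percentiles of the cilium and centrosome list were not taken after removal of a GC or length trend. The 44 members not seen beforehand had a median of −0.62, at percentile 8.23, and in the direct comparison lay at percentile 1.57. Developmental transcription factors had a median of 0.12 at percentile 99.2, with 4 of 30 higher and 2 lower, and 27 members not seen beforehand gave −0.01 at percentile 93.1, and 98.2 in the direct comparison. The 137 zinc finger genes had a median of −0.24 at percentile 98.3, with 1 higher and 15 lower, and their difference from the other genes turned from 0.18 to −0.24 with no CPM filter. Matrix and adhesion genes stood at percentile 46.4 in shHKDC1 and 99.9 in shRBBP5, where their median was 0.19. The 20 members not seen beforehand gave 0.06 in shRBBP5, at percentile 96.7. In the direct comparison the whole list lay at percentile 5.97 and those 20 members at 2.23. At a mean CPM of at least 5 the difference of that list from the other genes in shRBBP5 turned from 0.40 to −0.10. Cytokine genes in shHKDC1 (4 of 12 higher, 4 lower) and innate immune genes (1 of 16 higher, 2 lower) lay at percentiles 95.9 and 86.3. Of 8 lists, 4 fell outside the central 95% in shHKDC1, 1 in shRBBP5 and 4 in the direct comparison, and no chance rate applies to lists written after values had been seen.

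Of 27 measured genes on the liver-function list, 10 of them picked with their values in view, 17 were lower and 0 higher in shHKDC1. The list median of −1.45 lay below all 10000 matched random lists, while in shRBBP5 4 were lower with a median of −0.12. The bile acid enzyme BAAT (−2.16), complement C8A (−2.49), the acyltransferase MOGAT3 (−2.03) and the retinoic acid hydroxylase CYP26A1 (−1.32) were among the 17, and MOGAT3 and CYP26A1 were also lower in shRBBP5 (−2.03 and −1.44). The list median less that of the other genes was −1.07, and it stood at −1.13 after removal of a GC trend and −1.25 after removal of a length trend. The members had a higher GC content than the named genes (median 46.6% against 44.4%) and shorter transcripts (3047 against 4708 bases). Across named genes both went with higher ratios, so removing either trend was not likely to shrink the difference. It is the direction of the trends, not their removal, that argues against either as the whole cause for the 27 members, picked ones included. That direction does not bear on the members not picked. Without the 10 picked genes, the other 17 had a median of −0.47 at percentile 25.5. Of these 17, 8 were lower and 0 higher, where 22.1% of the 988 genes off the list were lower, a difference that was not tested, so the shift may come from the picking of members and a lower level of liver-function genes in shHKDC1 is a hypothesis that these data leave open.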
